A study of Homo sapiens with 12 samples.

How the data were processed

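Chromatin immunoprecipitation with sequencing was done in MV4-11 cells with a control guide (gNT) or an RNF4 guide (gRNF4), grown for 7 days in vehicle (DMSO) or 100 nM GSK3685032. The labels name 12 samples, which are 4 with DNMT1 antibodies, 4 with an H3K27ac antibody and 4 input samples, with 1 library per group. Per the labels, cells were crosslinked with formaldehyde and sonicated, and libraries were made with a ThruPLEX kit. The labels give the cell type as macrophage. Peak lists of the 8 antibody libraries were used. The input samples and signal tracks were not used here, so no read depth is known, and the precision given covers counts of peaks and genes only.

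Per the submitters' processing notes, reads were trimmed with cutadapt, aligned to GRCh38 with BWA, processed with Picard, and peaks were called with MACS2. deepTools is also named. Versions, duplicate handling, calling settings and whether an input served as control are not given in the sources used here. Each deposited list holds 1 library's peaks. The deposited score is the whole part of 10 times −log10 q, as checked on the values. The deposited fold is a ratio, the enrichment at the peak summit over a local background. Whether that background came from the same library or from an input is not given. The other deposited columns are −log10 p and −log10 q of the summit, and the lowest −log10 q was 1.30, which corresponds to a q of 0.05. Since folds and q depend on each library, they were used only within a list.

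The gene table (GRCh38.p14) gave 20033 protein-coding genes on chromosomes 1 to 22, X and Y. It holds no strand and no genome sequence was used, so the planned window around the 5′ end became 1000 bp around either gene end, overlapped by a peak by at least 1 bp. CpG content, repeats, exons and introns were not analysed here. For a condition and its reference, a gene gained a peak if only the condition had one and lost it if only the reference had one. The comparisons were inhibitor against DMSO within each guide and RNF4 guide against control guide within each treatment, for DNMT1 and for H3K27ac. Genes gained or lost in both pairs were counted beside the number given by the product of both shares among genes that could change that way in both pairs, a basis chosen after values over all genes were seen. Genes may differ in how readily a peak is called, so an excess over this number can arise without an effect of the condition. No test across samples was made. Each question has 2 pairs of single libraries, by guide or by treatment, and with 2 pairs an exact permutation test that flips the signs cannot give a two-sided p below 0.5.

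DNMT1 peaks at H3K27ac peaks were counted by an overlap of at least 1 bp, beside 20 random placements of the same peaks on the same chromosomes, with exact (Clopper-Pearson) 95% intervals. Genes with an acetylated end were longer than 5000 bp and had H3K27ac at the same end, and not at the other, in all 4 H3K27ac lists. Genes without H3K27ac had none in any of the 4 lists.

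The 17 gene lists were written before the data were examined. They cover maintenance of methylation, the SUMO and ubiquitin pathway, cancer-testis and germline genes, interferon and viral sensing, antigen presentation, MLL fusion targets, myeloid identity, stem and progenitor genes, genes hypermethylated in leukemia, imprinted genes, p53 targets, cell cycle and replication, ribosomal proteins, Polycomb-silenced developmental transcription factors, and lymphoid, erythroid and megakaryocyte, and non-hematopoietic genes. DDX58 and 3 imprinted RNA genes had no entry and were left out. Each list was set beside 10000 random lists matched on 3 classes of gene length, drawn among genes that could change. These were genes without a peak in the reference for gains and genes with one for losses, a choice corrected for losses after values were seen. The percentile is the share of random lists with a smaller count, with ties counted in part. A further match on H3K27ac (in none, some or all 4 lists) was added after seeing the data.

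Genes were named by a rule set before the data were examined. For each question, the 10 genes gained and the 10 lost in both pairs with the best mean rank of peak fold were named for DNMT1, and 5 each for H3K27ac. Up to 3 members of each list per direction were added, and the fixed panel DNMT1, RNF4, UHRF1, HOXA9, MEIS1, SPI1, CD14, DAZL, MAGEA1, CDKN2B and CDKN1A. Further list members with a call are named beside these, and some genes are not reported here. For each, it was checked whether the peak itself overlapped a peak of the other list.

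The alternatives planned were peaks with −log10 q of 5 or more, lists cut to equal length (69404 peaks for DNMT1 and 58842 for H3K27ac, by −log10 p and then fold), a window of 500 bp, and an overlap of at least 50% of the DNMT1 peak. The results for acetylated ends, genes without H3K27ac, net counts and list members under these settings were added after seeing the data, as was a rule that the peak itself overlap no peak of the other list. The counting was tested on simulated data. Of 100 gains and 100 losses planted in real lists, all were recovered with 0 others, and 4000 random lists had a mean percentile of 49.6. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.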

Results

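DNMT1 copies CpG methylation onto newly made DNA, and GSK3685032 is an inhibitor of DNMT1. RNF4 is a ubiquitin ligase that binds SUMO-modified proteins and marks them for degradation. The libraries came from MV4-11 cells, a leukemia line with an MLL fusion, carrying a control guide (gNT) or an RNF4 guide (gRNF4), after 7 days with vehicle (DMSO) or 100 nM GSK3685032. DNMT1 and H3K27ac, a mark of active promoters and enhancers, were each mapped in 1 library per group, so no replicate check exists for any value here and no test across samples was made. A gene is said to have a peak when a peak lies within 1 kb of either of its annotated ends. It gained or lost a peak when only the condition or only its reference had one. The fold of each peak is the authors' own value, read only within its own list. The confidence intervals are exact 95% binomial intervals and cover counting error only.

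With the inhibitor, DNMT1 peaks were found at more sites and lay less often at active chromatin. The ends of genes without H3K27ac, and of germline genes and developmental transcription factors, gained DNMT1 peaks, while acetylated gene ends lost them. Beside random lists matched on length and H3K27ac, the gains of the transcription factors lay outside the central 95% under both guides and those of germline genes under neither. Ribosomal protein, SUMO pathway and antigen presentation genes had fewer DNMT1 peaks with the inhibitor under both guides. Beside the same matched lists, their losses lay outside the central 95% under the RNF4 guide only. Among peaks with −log10 q of 5 or more the SUMO pathway genes had 5 members in both treatments under the control guide, and their losses lay within the range of random lists under both guides.

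The DNMT1 list of control-guide cells held 82238 peaks in DMSO and 147494 with the inhibitor. That of RNF4-guide cells held 69404 and 148934. Only 9929 (12.1%) and 10430 (15.0%) of the DMSO peaks had −log10 q of 5 or more, against 78686 and 79577 with the inhibitor. Calls of DNMT1 peaks lost with the inhibitor thus rest on lists of mostly weak peaks. The covered length went from 47.5 to 114 Mb with the control guide and from 40.8 to 120 Mb with the RNF4 guide. The H3K27ac lists varied less, between 58842 and 67302 peaks. Of the DNMT1 peaks with the inhibitor, 21.9% overlapped a DMSO peak in control-guide cells and 19.6% in RNF4-guide cells. Conversely, 43.5% and 46.6% of the DMSO peaks overlapped an inhibitor peak. Between the DMSO lists, 40.3% of RNF4-guide peaks lay at a control-guide peak and 34.4% the other way. The inhibitor lists are longer, so these shares do not compare directly with those above. In lists of equal length, 36.8% of RNF4-guide and 36.9% of control-guide DMSO peaks overlapped a DMSO peak of the other guide. An inhibitor peak of the same guide was overlapped by 33.6% and 31.7% of them. Peak summits at gene ends made up 15.4% and 18.3% of DNMT1 peaks in DMSO, against 6.37% and 6.79% with the inhibitor. Gene ends cover 2.36% of the genome.

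**Figure D1:**
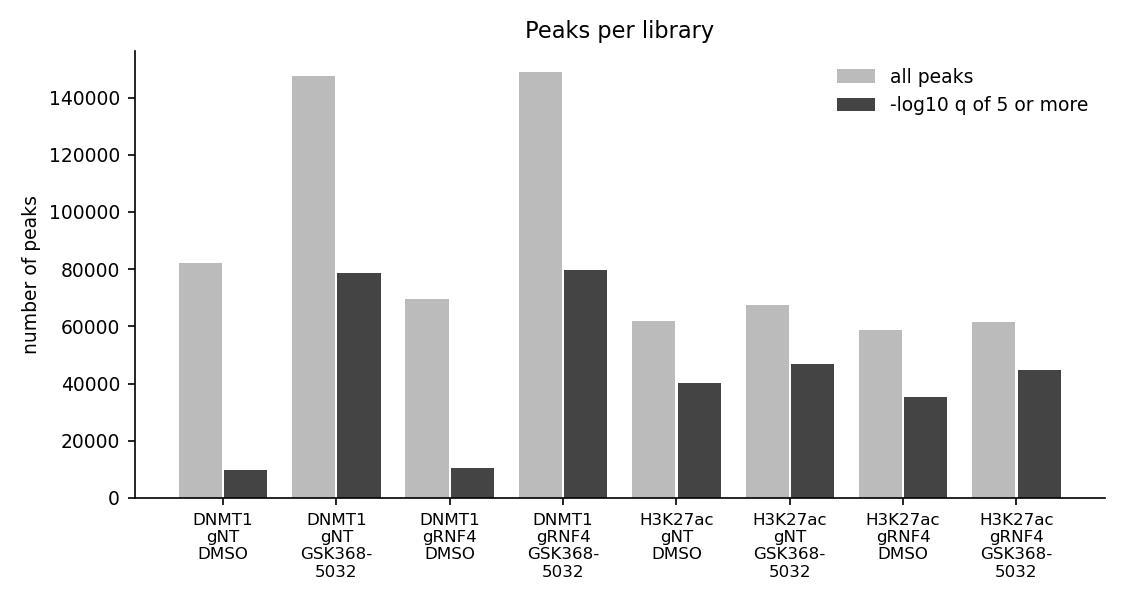
Number of peaks (vertical axis) in each of the 8 lists (horizontal axis), for all peaks and for peaks with −log10 q of 5 or more. The DNMT1 lists with the inhibitor hold 147494 and 148934 peaks, against 82238 and 69404 in DMSO, while the H3K27ac lists stay between 58842 and 67302.

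In control-guide cells 31.5% of DNMT1 peaks (31.2 to 31.8%) overlapped an H3K27ac peak in DMSO, and 12.2% (12.05 to 12.4%) with the inhibitor. In RNF4-guide cells the shares were 33.8% (33.4 to 34.1%) and 12.2% (11.9995 to 12.3%). Peaks placed at random overlapped H3K27ac in 4.62 to 5.39%, so both treatments stayed above that level. Of the H3K27ac peaks, 33.6% carried a DNMT1 peak in DMSO and 24.7% with the inhibitor under the control guide. Under the RNF4 guide these were 33.3% and 26.8%.

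**Figure D2:**
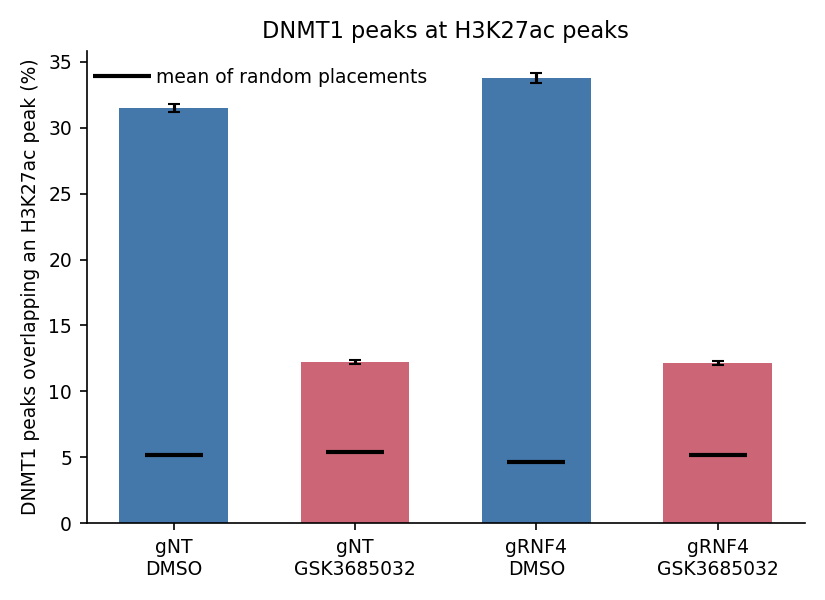
Percent of DNMT1 peaks that overlap an H3K27ac peak of the same guide and treatment (vertical axis), with exact 95% intervals, beside the same peaks placed at random. The share goes from 31.5% to 12.2% with the inhibitor under the control guide and from 33.8% to 12.2% under the RNF4 guide.

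Active genes usually carry H3K27ac at the end where transcription starts. In 7302 genes longer than 5000 bp with H3K27ac at 1 end only in all 4 lists, that end had a DNMT1 peak in 62.3% (61.2 to 63.5%) of control-guide genes in DMSO and 21.99% (21.0 to 22.96%) with the inhibitor. The opposite, unacetylated end of the same genes had one in 12.2% and 22.7%. RNF4-guide cells gave 70.9% (69.9 to 72.0%) and 28.05% (27.02 to 29.1%) at the acetylated end, and 9.38% and 22.6% at the opposite end. Of 6731 genes of any length without H3K27ac in any list, 29.3% (28.3 to 30.4%) had DNMT1 at either end in DMSO under the control guide. With the inhibitor 53.2% (52.0 to 54.4%) had it. Under the RNF4 guide these were 28.6% (27.5 to 29.7%) and 53.5% (52.3 to 54.7%). HOXA9 and SPI1, active in this kind of leukemia, had a peak at either end in all 8 lists. HOXA9 had H3K27ac at both ends throughout, and DNMT1 at both ends in DMSO but at 1 with the inhibitor, under both guides. The SPI1 peaks of DNMT1 and H3K27ac in RNF4-guide DMSO cells lay at opposite ends. MEIS1 had H3K27ac in all 4 lists and no DNMT1 peak in any. CDKN1A, a p53 target, had the same state as MEIS1.

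**Figure D3:**
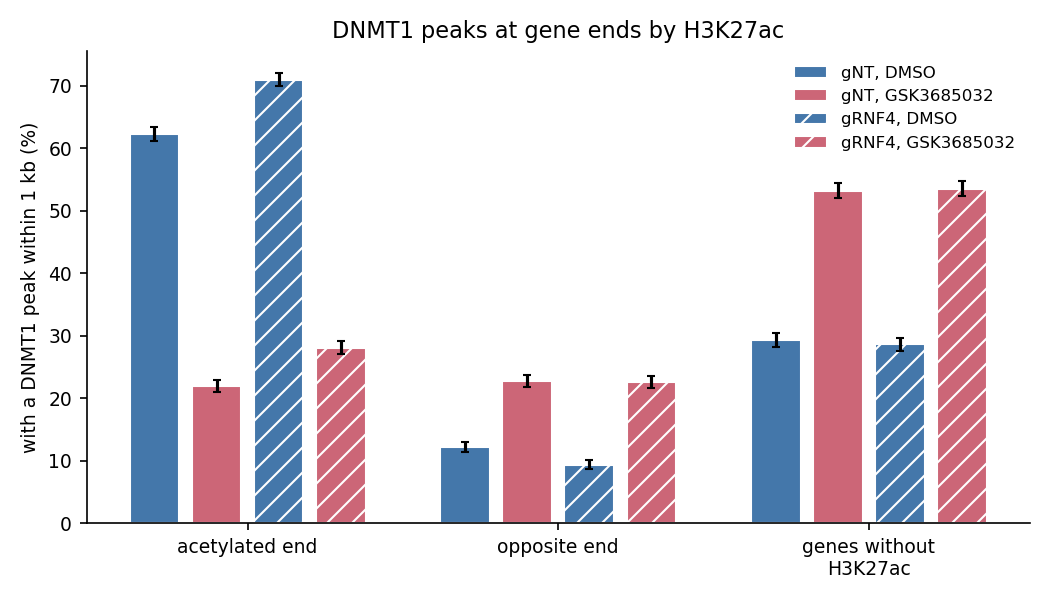
Percent with a DNMT1 peak (vertical axis), with exact 95% intervals, by guide and treatment. The acetylated end and the opposite end of 7302 genes longer than 5000 bp were each counted alone. For the 6731 genes without H3K27ac, of any length, a peak at either end counted. The level of these genes is therefore not comparable with that of single ends. Acetylated ends go from 62.3% to 21.99% under the control guide, and genes without H3K27ac from 29.3% to 53.2%.

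Counted by gene, 2871 genes gained and 4266 lost a DNMT1 peak in control-guide cells, and 2846 gained and 4190 lost one in RNF4-guide cells. In both guides 1417 genes gained a peak, against 480 if the guides were independent among genes that could gain one in both, and 2393 lost one, against 1014 on the same basis. The excess over independence alone does not show a shared effect of the inhibitor. Opposite calls were fewer, with 131 genes gained under the control guide and lost under the RNF4 guide, and 169 the other way. More genes lost than gained a peak in the lists as deposited, in lists of equal length (net −3023 under the control guide and −3760 under the RNF4 guide) and with a window of 500 bp (−1573 and −1849). Among peaks with −log10 q of 5 or more, the net went the other way, with 3974 more genes holding a DNMT1 peak with the inhibitor than in DMSO under the control guide and 3445 more under the RNF4 guide.

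Developmental transcription factors, listed here as Polycomb-silenced, gained a DNMT1 peak at nearly every member that lacked one. Their silencing in these cells was not measured here. In DMSO 32 of 48 had a DNMT1 peak under the control guide and 29 under the RNF4 guide, and 47 of 48 had one with the inhibitor under either guide. All 16 members that could gain a peak did so in control-guide cells, and 18 of 19 in RNF4-guide cells, where HOXD10 and HOXD11 shared a peak. No random list of genes matched for length, of 10000 drawn, reached these counts, which puts them at percentile 100. The random lists were not matched on CpG content. PAX3, SOX1, SIX6, TBX5, TBX15, OTX1, OTX2, HOXD13, NEUROG1 and BARHL2 gained a peak under both guides. The strongest were OTX2, SOX1 and BARHL2, with folds of 39.7, 26.5 and 24.02 in the control-guide list. At OTX2 in both guides and at BARHL2 in RNF4-guide cells, the peak also overlapped a DMSO peak that lay outside the 1 kb window.

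Cancer-testis and germline genes, which DNA methylation keeps silent outside the germline, had DNMT1 peaks at 8 of 42 members in DMSO under either guide. With the inhibitor 24 had one under the control guide and 23 under the RNF4 guide. The 14 that gained a peak under both guides were MAGEA10, MAGEA12, MAGEC1, PAGE2, PAGE5, CTAG2, DDX4, SYCP3, STK31, BRDT, CTCFL, ASZ1, DPPA2 and DPPA4. ASZ1 had the highest folds of these, 18.5 and 19.1, at its end on chromosome 7 (GRCh38, peak 117427094 to 117428026 in control-guide cells). The 17 gains of 34 possible ones lay at percentile 98.6 of random lists for the control guide and 97.4 for the RNF4 guide. Matched also on H3K27ac, they lay at 94.4 and 94.1. The random lists were not matched on chromosome, and the MAGEA, MAGEC, PAGE and CTAG genes lie on chromosome X. That chromosome held 275 DNMT1 peaks in DMSO and 2303 with the inhibitor under the control guide, and 330 and 1803 under the RNF4 guide. How far the germline gains reflect this was not tested. MAGEA1 had no DNMT1 peak in any list, and HORMAD1 lost one under both guides.

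Imprinted genes, whose parental copies differ in methylation, had DNMT1 peaks at 11 of 21 members in DMSO and 17 with the inhibitor under the control guide, and at 13 and 18 under the RNF4 guide. IGF2, DLK1, MEST, NNAT, NDN and NAP1L5 gained a peak under both guides, and MKRN3 lost one. Their gains, 8 of 10 and 7 of 8 possible, lay at percentile 99.9 for either guide. Genes often hypermethylated in leukemia had 17 of 28 in DMSO and 24 with the inhibitor under the control guide, and 21 and 23 under the RNF4 guide. In lists of equal length the RNF4 guide gave 21 in both treatments. DKK1, PGR, CALCA and LXN gained under both, and RASSF1 and APC lost. The PGR peak, and that of CALCA in control-guide cells, overlapped a DMSO peak. The gains, 10 of 11 and 6 of 7, lay at percentiles 100 and 99.4. CDKN2B of this group had a DNMT1 peak in DMSO under both guides and with the inhibitor under the control guide only.

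Stem and progenitor genes had DNMT1 peaks at 9 of 14 members in DMSO and 12 with the inhibitor under the control guide, and at 12 in both treatments under the RNF4 guide. The gains, 5 of 5 and 2 of 2 possible, lay at percentiles 99.7 and 93.2. Under the RNF4 guide they went from 12 to 10 in lists of equal length, from 4 to 11 among peaks with −log10 q of 5 or more, and from 7 to 12 with a window of 500 bp. CD34 gained a peak under both guides, and HOXB3 and SOX4 lost one. Genes of non-hematopoietic lineages went from 13 to 15 of 22 and from 12 to 15, with CDH2 gained under both guides, though in lists of equal length they went from 13 to 12 under the control guide. Erythroid and megakaryocyte genes had 8 of 15 in both treatments under the control guide and went from 7 to 11 under the RNF4 guide, with PF4 gained under both. In lists of equal length the RNF4 guide gave 7 in both treatments, and at −log10 q of 5 or more the control guide went from 3 to 8.

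The strongest DNMT1 peaks gained under both guides lay at genes of several kinds. The divergent pair MACROD2 and SEL1L2 shared a peak on chromosome 20 (13994901 to 13996619 in control-guide cells) with folds of 39.7 and 37.6. GABRA5, a GABA receptor subunit, had folds of 40.0 and 35.9, and the cadherin CDH2 39.7 and 33.4. HECW2, CYP2U1, TCERG1L and ANO4 followed, with folds of 32.0 to 37.0. None of these 8 genes had an H3K27ac peak at an end in any list. LOC124903827, SPON1 and PCDHA13 ranked among them, but in 1 guide each their peak overlapped a DMSO peak.

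Among the groups that lost DNMT1 peaks, ribosomal protein genes, which are active in growing cells, went from 24 to 12 of 32 members under the control guide and from 29 to 13 under the RNF4 guide. The losses, 15 of 24 and 17 of 29, lay at percentiles 99.8 and 99.9 of length-matched random lists. Matched also on H3K27ac, they lay at 95.7 and 98.1. All 32 carried H3K27ac in all 4 lists. RPL7, RPL8, RPL15, RPL23, RPL27, RPL32, RPS2 and RPS16 were among those that lost a peak under both guides, while RPS27 gained one. RPS2, RPL8 and RPL7 had the highest folds in DMSO, 5.61, 4.82 and 4.83 in the control-guide list.

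**Figure D4:**
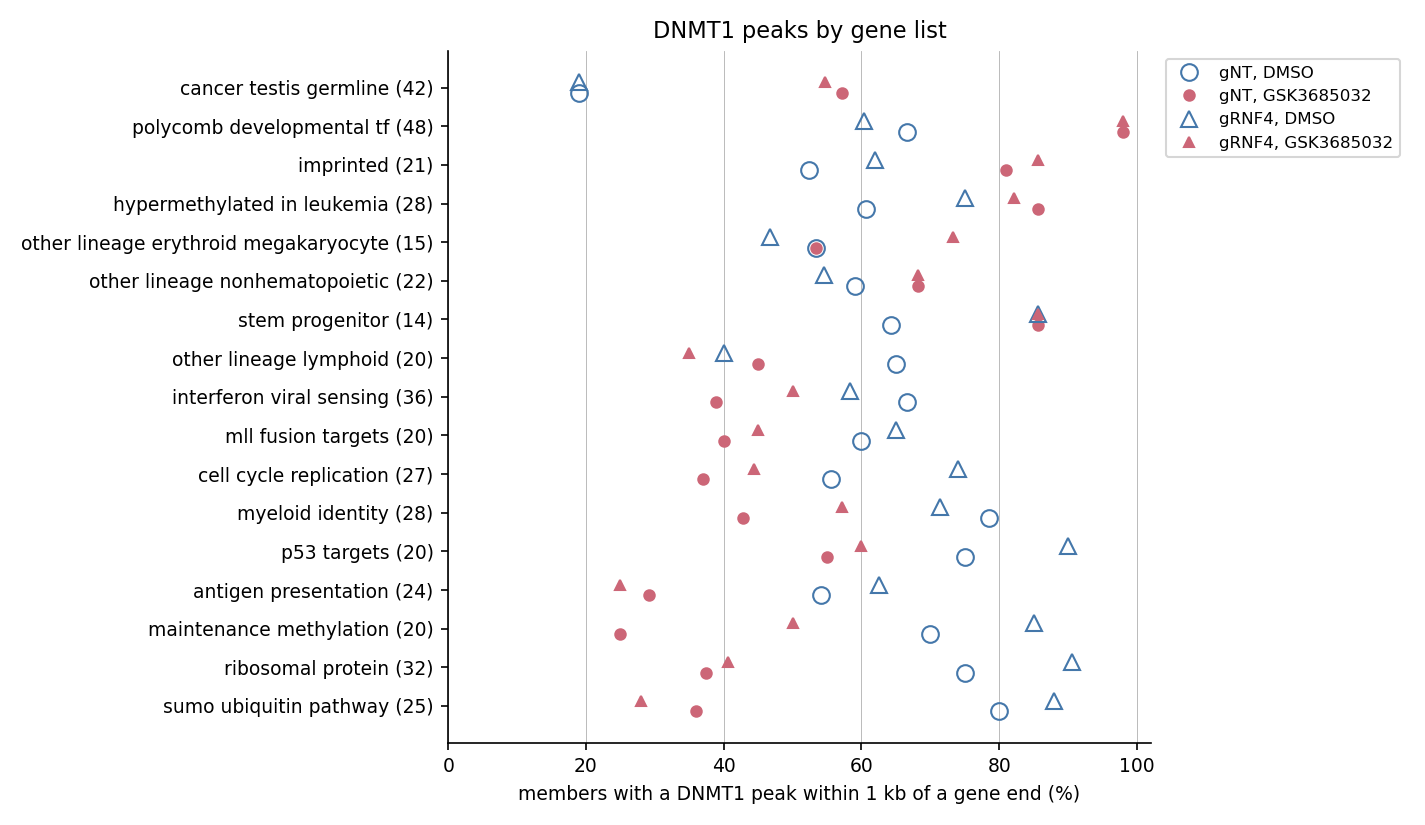
Percent of the members of each of the 17 fixed gene lists with a DNMT1 peak (horizontal axis), in DMSO (open markers) and with the inhibitor (filled markers), with circles for the control guide and triangles for the RNF4 guide. Polycomb-silenced transcription factors reach 47 of 48 members with the inhibitor under either guide, and ribosomal protein genes go from 24 to 12 and from 29 to 13 of 32.

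Genes of the SUMO and ubiquitin pathway, to which RNF4 belongs, went from 20 to 9 of 25 members under the control guide and from 22 to 7 under the RNF4 guide. RNF4, SAE1, PIAS1, PIAS3, SENP1, SENP2, SENP3, SENP5, SENP6, PML, UFD1 and SPRTN lost a peak under both guides, and PIAS2 gained one. The losses lay at percentiles 97.1 and 99.97, and at 80.3 and 99.2 matched also on H3K27ac. Antigen presentation genes, which help cells display peptides to T cells, went from 13 to 7 of 24 and from 15 to 6. HLA-B, HLA-C, HLA-E, B2M, PSMB8, NLRC5 and CD74 lost a peak under both guides, and HLA-DPA1 gained one. The losses lay at percentiles 96.5 and 99.9, and at 84.7 and 99.6 matched also on H3K27ac. The 11 losses under the RNF4 guide rested on 9 separate sites, since PSMB8, PSMB9 and TAP1 were linked by shared peaks.

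Genes that maintain DNA methylation went from 14 to 5 of 20 members and from 17 to 10. The losses lay at percentiles 96.5 and 64.9, and among peaks with −log10 q of 5 or more the members were 5 in both treatments under the control guide and 8 and 7 under the RNF4 guide. UHRF2, TET2, PCNA and CDCA7 lost a peak under both guides. The DNMT1 gene itself (chromosome 19) had a DNMT1 peak at both ends in DMSO under both guides. With the inhibitor it had one in RNF4-guide cells only, at its start by coordinate. Its other end, with H3K27ac in all 4 lists, had no DNMT1 peak with the inhibitor under either guide. UHRF1, the partner that brings DNMT1 to hemimethylated DNA, had a DNMT1 peak in all 4 lists, but not at the same end. Its start by coordinate, the only end with H3K27ac in any list, had one in both DMSO lists and neither inhibitor list. In RNF4-guide DMSO cells that peak was weak (−log10 q of 1.37). The p53 targets went from 15 to 11 of 20 and from 18 to 12, with MDM2, GADD45A, RRM2B, XPC and BTG2 lost under both guides and FAS gained. For FAS in control-guide cells and BTG2 in RNF4-guide cells, the peak overlapped one of the other list. Cell cycle and replication genes went from 15 to 10 of 27 and from 20 to 12, with MCM2 and TYMS lost under both. The losses of these groups lay within the range of random lists, at percentiles 59.3 and 66.4 for p53 targets and 87.6 and 66.9 for cell cycle genes. Among peaks with −log10 q of 5 or more the p53 targets had 7 in both treatments under the control guide, and 9 and 8 under the RNF4 guide.

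Interferon and viral sensing genes, which inhibitors of DNA methylation often switch on, went from 24 to 14 of 36 members and from 21 to 18. IFI6, MAVS and STING1 were among those that lost a DNMT1 peak under both guides, and IFI27 gained one. Myeloid identity genes went from 22 to 12 of 28 and from 20 to 16, with CEBPD, GFI1, CD33, S100A9 and LYN lost under both. Targets of MLL fusion proteins, which drive this leukemia, went from 12 to 8 of 20 and from 13 to 9, with CDK6, MYC, BCL2 and SENP6 lost under both. Lymphoid genes went from 13 to 9 of 20 and from 8 to 7, with CD79A and NKG7 lost under both. The losses of these 4 groups were also within the range of random lists, at percentiles 88.9 and 13.8 for interferon genes, 80.5 and 58.1 for myeloid genes, 64.8 and 90.2 for MLL targets and 36.9 and 61.6 for lymphoid genes. Among peaks with −log10 q of 5 or more these directions turned for interferon genes under the control guide (6 to 10 members), MLL targets under both (3 to 7 and 4 to 8), myeloid genes under the RNF4 guide (8 to 13), cell cycle genes under the control guide (2 to 6) and lymphoid genes under both (3 to 6 and 2 to 5). In the same lists ribosomal protein genes still went from 14 to 3 and from 15 to 6, and antigen presentation genes from 8 to 3 and from 9 to 5. SUMO pathway genes had 5 members in both treatments under the control guide and went from 7 to 5 under the RNF4 guide. There the SUMO pathway losses lay at percentiles 45.4 and 78.6, and the ribosomal protein losses at 99.99 and 99.8. With a window of 500 bp the MLL targets under the control guide also turned, to 1 more member with the inhibitor.

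The genes that lost the strongest DNMT1 peaks under both guides included ACTB, the cytoskeletal actin gene (folds of 7.06 and 6.02), and QSER1 (7.12 and 5.53), whose protein guards promoters against methylation. PHACTR2, FOXO3B, the histone gene H1-5, the pairs APTX with DNAJA1 and ARL3 with SFXN2, and LOC124903544 also lost one. At GIPR under both guides and GADD45B under the control guide, the peak overlapped one of the inhibitor list. Of all 264 list percentiles computed over the 8 comparisons, 28 lay outside the central 95%, against 13.2 by chance, and 14 of the 28 came from these inhibitor comparisons of DNMT1.

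H3K27ac at gene ends differed less between inhibitor and DMSO than DNMT1 did. In control-guide cells 718 genes gained and 463 lost an H3K27ac peak, and in RNF4-guide cells 636 gained and 508 lost one. In both guides 264 genes gained a peak, against 28.7 if independent among genes that could gain one in both, and 133 lost one, against 4.64. This excess alone does not show a shared effect of the inhibitor. Opposite calls were fewer, with 54 genes gained under the control guide and lost under the RNF4 guide, and 40 the other way. Germline genes that are silent in blood cells, an interferon gene and an HLA class II gene were among those gained.

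DAZL, a germ cell RNA-binding protein gene, had a DNMT1 peak in all 4 lists and H3K27ac with the inhibitor only (folds of 11.95 and 5.32, at 16604337 to 16605344 on chromosome 3 in control-guide cells). MAGEA12, IFIT3, HLA-DQB1, SFRP4, LXN and OLIG2 also gained H3K27ac under both guides, with folds of 3.23 to 6.42. MAGEA12 and LXN gained DNMT1 too. MAGEA4 and HOXD13 gained H3K27ac as well, but their peaks overlapped DMSO peaks under both guides. The same held for SHISA7, ZNF569, DPF1 and NOTO, which ranked highest, and for WDR97 in control-guide cells. MAGEA1 gained H3K27ac in control-guide cells only. Cancer-testis genes with H3K27ac went from 7 to 12 of 42 under the control guide and from 6 to 10 under the RNF4 guide. These gains lay at percentiles 88.1 and 78.2. Polycomb-silenced transcription factors went from 7 to 11 of 48 under either guide, with gains at percentiles 81.3 and 85.9. Antigen presentation genes went from 20 to 22 and from 17 to 21 of 24, with gains at percentiles 97.6 and 99.9. Erythroid and megakaryocyte genes lost 2 of 7 under the control guide (98.3) and 1 of 6 under the RNF4 guide (86.7). EPHB2, BLNK and GP1BA lost an H3K27ac peak under both guides, and so did CD79B, whose peak overlapped one of the inhibitor list in control-guide cells. The peaks of DIPK1B, AFAP1L1, LANCL3 and SERPINB13, also lost, overlapped inhibitor peaks under both guides. CDKN2B kept H3K27ac in all 4 lists, and CD14, a monocyte marker, lacked it only in RNF4-guide cells with the inhibitor.

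Genes that gained or lost H3K27ac under both guides often carried DNMT1 throughout. Of the 264, 47.0% (40.8 to 53.2%) had a DNMT1 peak in all 4 lists, against 20.9% of 7408 background genes without H3K27ac in DMSO. Of these genes 0.758% (0.0919 to 2.71%) had lost a DNMT1 peak under both guides, against 0.378% of the background, and 14.8% gained one, against 15.5%. Of the 133 genes that lost H3K27ac, 8.27% (4.20 to 14.3%) gained DNMT1 under both guides, against 1.55% of 11707 background genes with H3K27ac in DMSO. They lost DNMT1 in 3.01%, against 20.04%, and had it in all 4 lists in 42.9% (34.3 to 51.7%), against 30.5%.

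RNF4 itself had a DNMT1 peak in DMSO under both guides and none with the inhibitor, and H3K27ac in all 4 lists. Its peaks do not show whether the guide removed the protein. The RNF4 guide left fewer shared differences than the inhibitor did. In DMSO 2612 genes gained and 2034 lost a DNMT1 peak against the control guide, and with the inhibitor 1616 gained and 987 lost one. In both treatments 220 genes gained a peak, against 129 if the treatments were independent among genes that could gain one in both, and 128 lost one, against 86.6. Opposite calls were also many, with 131 genes that gained a peak in DMSO and lost it with the inhibitor, and 169 the other way. The DNMT1 gene lists gave few members in both treatments, which were KLF4 gained, and FCN1, MCM4, CD3D and CD3G lost. CD3D and CD3G shared a peak in each control-guide list, so they count as 1 site.

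The DNMT1 lists of both guides overlapped less in DMSO than with the inhibitor. In DMSO 40.3% of RNF4-guide peaks overlapped a control-guide peak, and with the inhibitor 63.7% did. Within DMSO, cell cycle genes gained 8 of 12 possible peaks (percentile 99.5), ribosomal protein genes 5 of 8 (98.9), stem and progenitor genes 4 of 5 (98.0), and lymphoid genes lost 6 of 13 (99.2). With H3K27ac also matched, these percentiles were 81.2, 72.5, 99.5 and 97.2. The 6 lymphoid losses rested on 5 separate sites. At the low end, ribosomal protein genes lost 0 of 24 (0.660), SUMO pathway genes lost 0 of 20 (0.735) and cancer-testis genes gained 3 of 34 (0.715). Matched also on H3K27ac, these lay at 4.09, 2.48 and 8.54, and among peaks with −log10 q of 5 or more ribosomal protein genes lost 7 of 14. With the inhibitor ribosomal protein genes lost 5 of 12 (99.7) and gained 6 of 20 (95.6), so that the total went from 12 to 13. Among peaks with −log10 q of 5 or more they lost 0 of 3. Polycomb-silenced transcription factors lost 0 of 47 (0.415) and cancer-testis genes gained 0 of 18 (2.33), at 0.940 and 5.83 when matched also on H3K27ac. The strongest peaks gained in both treatments lay at GLCCI1 (folds of 7.14 and 4.74), CORO7-PAM16, HSF2, a heat shock factor gene, ERI3, KIFC1, CWF19L1, HEG1, RNF187, IFTAP and RAB21. The KLF4 peak overlapped a control-guide peak in both treatments. The strongest peaks lost lay at WDR31, FAM24A, SLC19A1, a folate carrier gene, CCDC182, VCF2, MTRFR and TCP10L. LBP, LOC112267855 and CEACAM5 were also among them, each with a peak that overlapped an RNF4-guide peak in 1 treatment.

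For H3K27ac the RNF4 guide gave 404 genes gained and 514 lost in DMSO, and 282 gained and 519 lost with the inhibitor. In both treatments 28 genes gained a peak, against 4.98 if independent among genes that could gain one in both, and 66 lost one, against 4.01. Opposite calls were as common, with 54 genes that gained H3K27ac in DMSO and lost it with the inhibitor, and 40 the other way. With the inhibitor Polycomb-silenced transcription factors lost H3K27ac at 3 of 11 (percentile 99.3) and gained it at 3 of 37 (90.1), so that 11 had it under either guide. LCK, a T cell kinase gene, and RHEX gained H3K27ac in both treatments, and AREG, which encodes a growth factor, lost it. UHRF1 lacked H3K27ac in RNF4-guide DMSO cells only. ATF3, a stress response gene, ranked among the genes gained with PLCH2, LBHD2 and SYN2, but their peaks overlapped control-guide peaks in both treatments. So did those of CPNE9, SIAH1 and RAB11FIP5 among the genes lost, and that of ASB16 with the inhibitor. In DMSO 72.5% of RNF4-guide H3K27ac peaks overlapped a control-guide peak, and with the inhibitor 79.4% did.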

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

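The tests on list length and on the calling threshold were chosen after the result was seen, and the test on background pull-down before.

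The inhibitor gave more DNMT1 peaks, and fewer of them lay at H3K27ac, under both guides. If longer lists only added weak peaks away from acetylated sites, lists of equal length would level the shares, but the smaller of both differences was still 20.3 percentage points, which argues against list length as the whole cause. Background pull-down of open chromatin in the DMSO libraries stays open and could account for DNMT1 peaks at acetylated ends. The 25% of ends with the highest H3K27ac fold had a DMSO DNMT1 peak 0.970 times as often as the 25% with the lowest under the control guide (63.5% against 65.5%) and 1.14 times as often under the RNF4 guide (75.7% against 66.1%), which neither excludes it nor bears it out. A redistribution of DNMT1 by the inhibitor remains an untested biological explanation, since no replicate and no input file was used.

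The RNF4 guide had fewer DNMT1 peaks than the control guide in DMSO (by −12834) and more with the inhibitor (by 1440), opposite directions whose gap of 14274 peaks was not tested. Peaks near the calling threshold may explain the DMSO deficit. Among peaks with −log10 q of 5 or more the RNF4 guide had 1.05 times as many as the control guide in DMSO. The covered length went the same way, by −6.68 Mb in DMSO and 6.09 Mb with the inhibitor, a gap of 12.8 Mb. An effect of RNF4 loss remains an untested biological explanation.

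Other differences between the RNF4 guide and the control guide also had opposite directions in DMSO and with the inhibitor, and none was tested. Each rests on 1 library per group, and such opposite directions arise by chance about as often as equal ones where there is no effect. The share of DNMT1 peaks at H3K27ac differed by 2.29 points in DMSO and −0.0489 points with the inhibitor, a gap of −2.34. The share of genes without H3K27ac that had DNMT1 differed by −0.758 and 0.297 points, a gap of 1.05. The number of members with a DNMT1 peak differed by 2 and −2 for the SUMO pathway (gap −4), by −3 and 4 for interferon genes (gap 7), and by 2 and −1 for antigen presentation (gap −3). It differed by −2 and 4 for myeloid genes (gap 6), by 4 and −1 for genes hypermethylated in leukemia (gap −5), and by −1 and 3 for erythroid and megakaryocyte genes (gap 4).

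For H3K27ac, the inhibitor's effect on the number of members had opposite directions in the control guide and the RNF4 guide for myeloid genes (1 and −2, gap −3) and for non-hematopoietic genes (1 and −1, gap −2), not tested. The RNF4 guide's effect had opposite directions in DMSO and with the inhibitor for myeloid genes (1 and −2, gap −3), hypermethylated genes (−1 and 1, gap 2), erythroid and megakaryocyte genes (−1 and 1, gap 2) and non-hematopoietic genes (1 and −1, gap −2), also not tested.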

How the results depend on the processing

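The results for acetylated ends, genes without H3K27ac, net counts and gene lists under other settings, and the rule that the peak itself overlap no peak of the other list, were chosen after the result was seen. The other settings were planned. Each question was repeated in 2 pairs, by guide or by treatment, and the values are given for each pair without a test. The cause of the differences below was not tested, except that a stricter threshold, a narrower window or a larger overlap leaves fewer peaks or genes by construction.

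Under every setting run, the share of DNMT1 peaks at H3K27ac was lower with the inhibitor under both guides, acetylated ends had fewer DNMT1 peaks, and genes without H3K27ac had more. With peaks of −log10 q of 5 or more, the shares at H3K27ac in DMSO and with the inhibitor were 51.3% and 9.52% under the control guide and 56.5% and 10.3% under the RNF4 guide. Acetylated ends gave 20.6% and 12.9%, and 31.6% and 18.5%. Genes without H3K27ac gave 7.504% and 49.6%, and 8.34% and 50.2%. The net number of genes with the inhibitor turned from −1395 to 3974 and from −1344 to 3445. Genes that gained DNMT1 with the inhibitor became 5592 under the control guide, 5493 under the RNF4 guide and 3955 in both, and those that lost it 1618, 2048 and 601. The RNF4 guide's DNMT1 losses in both treatments became 60, its H3K27ac gains 198 in DMSO and 14 in both treatments. H3K27ac losses with the inhibitor became 250 under the RNF4 guide and 88 in both.

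In lists of equal length, the shares at H3K27ac became 32.4% for the control guide in DMSO and 13.5% for the RNF4 guide with the inhibitor. Acetylated ends gave 57.5% and 12.9% under the control guide and 18.1% for the RNF4 guide with the inhibitor. Genes without H3K27ac gave 27.9% and 47.0%, and 47.0%. The RNF4 guide's DNMT1 losses in both treatments became 70. Requiring 50% of the DNMT1 peak to be covered gave 26.5% and 8.51%, and 28.5% and 8.35%. A window of 500 bp gave 56.4% and 15.6%, and 66.8% and 19.05%, at acetylated ends, and 25.1% and 49.9%, and 25.1% and 50.5%, at genes without H3K27ac.

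The inhibitor's effect on list members with a DNMT1 peak turned, at −log10 q of 5 or more, to 4 for interferon genes, 4 for MLL targets and 4 for cell cycle genes under the control guide, to 4 for MLL targets and 5 for myeloid genes under the RNF4 guide, and to 3 for lymphoid genes under either. It turned to 1 for MLL targets under the control guide with a window of 500 bp, and to −1 for non-hematopoietic genes under that guide in lists of equal length. Of the remaining shares and counts of gained and lost genes, 13 stayed within their interval or within 1.5 times at −log10 q of 5 or more, 27 in lists of equal length and 24 with a window of 500 bp. Among the net counts, list members and list percentiles, 66, 18 and 30 stayed so in these settings, and 35, 23 and 11 shifted without turning to the opposite direction. The 24 counts of gained and lost genes stayed within 1.5 times under the rule that the peak itself overlap no other peak. Matching random lists on H3K27ac left 65 of 68 DNMT1 percentiles of the inhibitor, and 59 of 68 of the RNF4 guide, on the same side of the central 95%. The read depth is unknown, so how many absent peaks a deeper library would have cannot be said.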

Other observations

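The test on the gene density of chromosome X was chosen after the result was seen, and the test on its copies before.

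Chromosome X had few DNMT1 peaks at acetylated gene ends. In DMSO 15.4% of them had one under the control guide and 28.5% under the RNF4 guide, while no autosome was below 55.8% and 65.4%. The tables argue against low gene density as the cause. With 5.43 genes per Mb, X held more than the 4 autosomes with the fewest (2.96 to 4.92). It still lay at least 39.7 points below the lowest share among them. Fewer DNA copies of X, which would leave weak peaks under the threshold, may explain part of the low share, but this stays open. The share of X among weak H3K27ac peaks was at most 0.721 times that among strong ones in the 4 lists, as this would need. Both DNMT1 lists in DMSO, which show the pattern, ran the other way, with X at 0.347% of weak and 0.213% of strong peaks under the control guide, and at 0.514% and 0% under the RNF4 guide. These lists held only 937 and 1451 strong peaks (−log10 q of 10 or more) on all chromosomes. The strong shares of X thus rest on very few peaks, too few to settle a direction under the control guide.

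Chromosome 19, rich in genes, held 13.0% of DNMT1 peaks in DMSO and 7.45% with the inhibitor under the control guide, and 12.3% and 8.03% under the RNF4 guide. In DMSO, 87.1% and 85.9% of its acetylated gene ends had a DNMT1 peak under the control and RNF4 guides. On chromosome 8, with 4.92 genes per Mb against 24.8, these shares were 76.0% and 88.6%. The reason was not tested. DNMT1 peaks lay within 5 Mb of a chromosome end in 22.1 to 24.1% of cases over the 4 lists, and H3K27ac peaks in 13.6 to 15.4%, where such regions make up 7.77% of the genome. Peaks wider than 5 kb numbered 11 and 5 in the DMSO DNMT1 lists and 755 and 928 in the inhibitor lists.

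Gene families by symbol were counted after the data were examined. Among the clustered protocadherins, neuronal adhesion genes, 3 of 13 PCDHA genes had a DNMT1 peak in DMSO under the control guide and 6 under the RNF4 guide, and all 13 with the inhibitor under both. The 16 PCDHB genes went from 1 to 15 and from 3 to 13. A peak at an end that several genes share counts for each of them. Separate peaks were not counted for PCDHA or PCDHB, so these calls may not all be separate gains. The 12 PCDHGA genes, which share 1 end in the gene table, had no such gain, since all had DNMT1 and H3K27ac peaks in all 4 lists of each. Olfactory receptor genes went from 15 to 49 of 392 and from 19 to 46, keratin-associated proteins from 13 to 27 of 94 and from 14 to 24, and collagens from 21 to 35 of 44 and from 27 to 34. Replication-dependent and other histone genes went the other way, from 52 to 22 of 87 and from 49 to 22. Mitochondrial ribosomal large-subunit genes went from 31 to 12 of 49 and from 27 to 14, and translation initiation factors from 30 to 19 of 56 and from 43 to 21. These directions were counted for the lists as deposited only.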
